A study of Mus musculus with 6 samples.

How the data were processed

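Total RNA of hearts and isolated cardiomyocytes of male mice aged 4 to 6 months was hybridized to Illumina MouseWG-6 bead arrays, on which each transcript is read by beads that carry a short probe. Per the labels, 500 ng of RNA per sample was copied to cDNA and transcribed into biotin-labelled cRNA. The inducible cardiac-specific SIRT1 knockout (KO) was made with tamoxifen (0.08 mg/g for 5 days) given at 12 weeks of age to mice with a floxed Sirt1 gene and a tamoxifen-inducible Cre recombinase. Whether wild-type (WT) mice were injected is not given in the sources used here. Ischemia/reperfusion (I/R) was 45 min of ischemia followed by 24 h of reperfusion, per the sample titles.

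The authors read the arrays with GenomeStudio 2011.1, per the submitters' processing notes, and the file headers give module version 1.9.0. Per the file headers, the deposited non-normalized probe table holds the mean bead intensity per probe without background subtraction. The same deposited table holds the bead standard error in intensity units, the number of beads, and a detection p-value, which is the share of negative control beads at or above the signal of the probe. A second deposited probe table holds intensity after background subtraction and quantile normalization by the authors. The deposited series values were compared with it and were equal for 271686 of 271686 values. A deposited gene-level table holds non-normalized intensity and detection p-values per gene, and a deposited sample table holds the mean intensity of the control classes and counts of detected genes. The normalized gene-level table was not used, because it repeats the probe-level one per gene. Array columns were matched to samples by the sample identifier in the labels, and 0 columns were left unmatched.

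Non-normalized probe intensities were background corrected, offset by 16, quantile normalized and put on the log2 scale with neqc of limma 3.58.1 in R 4.3.3, taking the negative control signal from the detection p-values. Python 3.11.15 with matplotlib 3.10.9 drew the plots. Probes with a detection p-value under 0.01 on at least 1 array were kept (17097 of 45281). A gene took the value of its brightest kept probe by mean over the 6 arrays, which left 12600 genes. Probe symbols were updated through their Entrez IDs, of which 29586 of 31508 were found in the reference table. The genome build of the probe coordinates is not given in the sources used here.

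Each of the 6 groups (WT or KO basal heart, I/R heart and cardiomyocytes) held 1 array, all on 1 slide. Differences between single arrays were therefore not tested. They are given as log2 differences with the standard error from the beads of both arrays, which covers bead-to-bead error on the array and neither animals nor handling. Genes at or beyond a 2-fold difference were counted among genes with a detection p-value under 0.01 on every array of the comparison. A gene with a detection p-value of 0.05 or more on one side and under 0.01 on the other is given as a bound, taken against the lowest detected value of the dimmer array. The comparisons were KO minus WT in each condition, I/R minus basal heart in each genotype, the difference of those 2 responses, and cardiomyocytes minus basal heart in each genotype. The last pair was added as a description of the arrays behind the averaged effect.

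The only tests between arrays came from an additive limma fit of genotype and condition to all 6 arrays, with 2 residual degrees of freedom and 5.70 prior degrees of freedom. It gave the genotype effect averaged over 3 conditions, the I/R effect averaged over 2 genotypes, and cardiomyocytes minus basal heart averaged over 2 genotypes. P-values were two-sided and adjusted by Benjamini-Hochberg over all genes, and genes were called at an adjusted p-value under 0.05. Any difference between conditions in the genotype effect enters the residual of this fit and widens its errors.

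A total of 35 gene lists (metabolism, stress responses, inflammation, cell type markers, cardiac programmes and a check of the sex given in the labels) was fixed from general knowledge. In single comparisons a list is described by the median log2 difference of all its measured members and by the percentile of that median among 10000 random lists of the same size, matched on expression in 20 bins. A list whose median lies outside the central 95% of them is said to stand outside its random lists. This describes the arrays and is no test between animals, since genes are not replicates. In the averaged effects the lists were tested with camera of limma with a preset inter-gene correlation of 0.01, adjusted over the lists, and again with an estimated correlation. The latter also takes its p-values from the 2 residual degrees of freedom, so that a list can hardly pass. Circadian genes had an estimated correlation of -0.05, and their camera p-value for the I/R effect still went from 0.000304 to 0.0626. A count of 0 lists with an estimated correlation therefore decides little. For each list the genes passing 0.05 when adjusted over the list alone were also counted.

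The fit was tested on simulated data with 200 changed genes among 12600. These were drawn with the moderated variances of the fit, which are already pulled toward a common value. At a log2 size of 1 it recovered 55.5% of changed genes for the genotype effect, 29 of 200 (14.5%) for the I/R effect and 47 of 200 (23.5%) for cardiomyocytes minus basal heart. At a log2 size of 2 the shares were 99.5%, 99.5% and 100%, and at a log2 size of 3 they were 100% in each. The drawn data held no difference between conditions in the genotype effect, so these shares do not carry over to genes that have one. On the arrays the limma fit gave Il1b a genotype effect of 4.30 (SE 0.59, adjusted p = 0.407), which was not called. A count of 0 genes therefore does not exclude changes of this size.

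The genes named were chosen by a rule. Sirt1 came first. In averaged effects the rule took the 10 largest rises and falls among called genes, and in single comparisons the 10 largest differences each way (5 for I/R within a genotype and for the difference of responses) among genes detected on every array of the comparison, plus 3 bounds each way. Clone and predicted-gene identifiers were counted and not named. From each list up to 4 detected members with the largest absolute difference were taken. Because 0 genes were called in the averaged effects, the genes named there, with small p-values and detected on every array, and those named from the fit of the 4 heart arrays, were chosen after their values were seen. No gene named by its rank in a single comparison or as a list member had another detected probe that differed in sign and passed 2-fold. The other named genes were not checked in this way.

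The gene lists, the tests, the naming rule and these alternatives were fixed before the data were examined: the authors' quantile values, the series values, no background correction, median scaling, an offset of 50, a detection p-value under 0.05, no detection filter, the mean of detected probes, the gene-level table, leave-one-out, moderated variances with trend and robust options, the 4 heart arrays alone, a difference beyond 3 bead standard errors, and an estimated correlation in camera. Chosen after seeing the data were camera on the 4 heart arrays, camera after median scaling, and counts without the members of marker lists that stood apart. After the list results had been computed and seen, the matching of list symbols was changed to prefer the exact spelling, because Sparc had been matched to another probe spelled in capitals. This moved values of the fibroblast list and the adjusted p-values that depend on it.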

Results

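Gene expression was measured on 6 Illumina MouseWG-6 arrays of heart tissue and isolated cardiomyocytes from male wild-type (WT) mice and mice with an inducible cardiac-specific knockout of SIRT1 (KO). SIRT1 is a deacetylase that uses NAD. Each genotype gave 1 array of basal heart, 1 of heart after ischemia/reperfusion (I/R, 45 min of ischemia and 24 h of reperfusion) and 1 of cardiomyocytes, so no group had replicates. The deposited sample table counts between 8231 (KO basal heart) and 9074 (WT I/R heart) genes detected per array at a detection p-value under 0.01. All counts that follow take a gene as detected where its brightest kept probe is, which held on all 6 arrays for 9070 of the 12600 genes kept. The mean signal per array ran from 346 in KO cardiomyocytes to 453 in the KO I/R heart, over a negative control signal of 107 to 123.8. The median number of beads per probe was 41 or 42. Pearson correlations between arrays across genes, which are not independent replicates, ran from 0.939 for KO basal heart and KO cardiomyocytes to 0.979 for the cardiomyocyte arrays of both genotypes. The number of arrays limits the precision of every value. Differences between single arrays are given on the log2 scale as value ± standard error from the beads, and were not tested.

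The Sirt1 transcript was not lower on any KO heart or cardiomyocyte array by more than its bead error. Sirt1 (Entrez Gene 93759, chromosome 10) was read by 1 probe, at positions 62782384 to 62782433 in the deposited file, which starts at base 3211 of the transcript. Its log2 level was 7.31 in WT and 8.11 in KO basal heart, a difference of 0.80 ± 0.19. KO minus WT was -0.06 ± 0.11 in I/R heart and -0.06 ± 0.15 in cardiomyocytes. Averaged over the 3 conditions the difference was 0.23 (SE 0.24, adjusted p = 0.732). The probe lies in the 3' part of the transcript, and whether the floxed exons were lost was not measured by it. Genotype is therefore used here as the labels give it. KO mice also carried a Cre recombinase and were given tamoxifen, and whether WT mice were is not given in the sources used here, so KO minus WT holds any effect of these beside that of the deletion.

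The genotype effect asks what cardiac SIRT1 deletion changed on average over basal heart, I/R heart and cardiomyocytes. Inflammatory cytokine and NF-kB target genes and immediate early genes stood higher in KO, and red cell, mesothelial, fatty acid oxidation and TCA cycle genes stood lower. None of these lists was called by camera with an estimated correlation, where the smallest adjusted p = 0.652. With 2 residual degrees of freedom that setting could hardly call a list. Genes detected on every array with small p-values included the phosphodiesterase Pde4b (log2 1.56, SE 0.19), the stress transcription factor Ddit3 (1.64, SE 0.22), the metalloproteinase inhibitor Timp1 (1.32, SE 0.21), asparagine synthetase Asns (1.64, SE 0.27) and the nicotinamide riboside kinase Nmrk2 (1.69, SE 0.28). None of these passed the adjustment over all genes. The additive limma fit called 0 genes at an adjusted p-value under 0.05, with 1249 genes at an unadjusted p-value under 0.05 (658 higher, 591 lower) where 630 were expected, and the smallest adjusted p = 0.407. A total of 4358 genes had the same sign in all 3 pairs of arrays, and 11 of them were also at or beyond 2-fold in each pair. With moderated variances that use trend and robust options 8 genes were called. Differences between conditions in the genotype effect enter the error of this fit.

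Of the 35 gene lists, 9 were called for the genotype effect by camera with the preset correlation, and 0 with an estimated correlation. The inflammatory list rose with a median log2 of 1.61 (adjusted p = 2.38e-15, and adjusted p = 0.652 with an estimated correlation), with medians of 2.33 and 2.60 in basal and I/R heart and 0.02 in cardiomyocytes, where 14 genes were higher and 13 lower. Of its 27 genes, 16 passed when adjusted over the list alone, and 0 over all genes. The immediate early list, genes induced within minutes of a stimulus, rose with a median of 1.34 (adjusted p = 3.91e-15, and adjusted p = 0.652 with an estimated correlation), with 15 of 21 genes passing when adjusted over the list alone. Red cell and platelet genes fell by 1.40 at the median (adjusted p = 9.23e-06, and adjusted p = 0.652 with an estimated correlation), and 4 of 10 passed when adjusted over the list alone. Mesothelial markers (median -0.88, adjusted p = 0.000793), TCA cycle genes (-0.29, adjusted p = 0.000793) and fatty acid oxidation genes (-0.27, adjusted p = 0.00215) fell, each with adjusted p = 0.652 with an estimated correlation. Of these, 3 of 6 mesothelial, 0 of 20 TCA cycle and 0 of 23 fatty acid oxidation genes passed when adjusted over the list alone. Cardiac ion channel and calcium handling genes stood at -0.32 (adjusted p = 0.00215, and adjusted p = 0.678 with an estimated correlation), with 0 of 23 passing when adjusted over the list alone. Fibroblast and matrix genes (median 0.24, adjusted p = 0.00462, and adjusted p = 0.652 with an estimated correlation) and cytosolic ribosomal proteins (median 0.16, adjusted p = 0.0131, and adjusted p = 0.682 with an estimated correlation) rose, with 1 of 25 and 0 of 27 genes passing when adjusted over the list alone. The fibroblast median was higher in 2 of 3 pairs and stood at -0.03 between the basal hearts. The other called lists had medians of 1 sign in 3 of 3 pairs. Some were near 0 between the basal hearts, at -0.07 for ion channels, 0.08 for ribosomal proteins and -0.14 for the TCA cycle, whose sign there turned under median scaling.

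The number of genes called for the genotype effect averaged over 3 conditions changed with the arrays that entered. Without either cardiomyocyte array the fit is that of the 4 heart arrays, with 1 residual degree of freedom, and it called 617 genes (369 higher, 248 lower). In that fit the chemokine Ccl4 rose by 7.13 (SE 0.27), Il1b by 5.38 (SE 0.27) and the inducible heat shock protein Hspa1a by 5.94 (SE 0.27) on the log2 scale. Fos rose by 4.22 (SE 0.55) and Nmrk2 by 2.03 (SE 0.27), while the globin Hba-a1 fell by 6.98 (SE 0.29) and Col1a1 by 1.08 (SE 0.27). With 34.5 prior degrees of freedom, these errors rest mostly on the variance shared by all genes and hardly on the spread of each gene. The prior degrees of freedom were 379 without WT or without KO basal heart and 3.24 without either I/R array, and the counts called depend on them. Without WT or without KO basal heart 102 genes were called, and without either I/R array 0 were called.

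**Figure D1:**
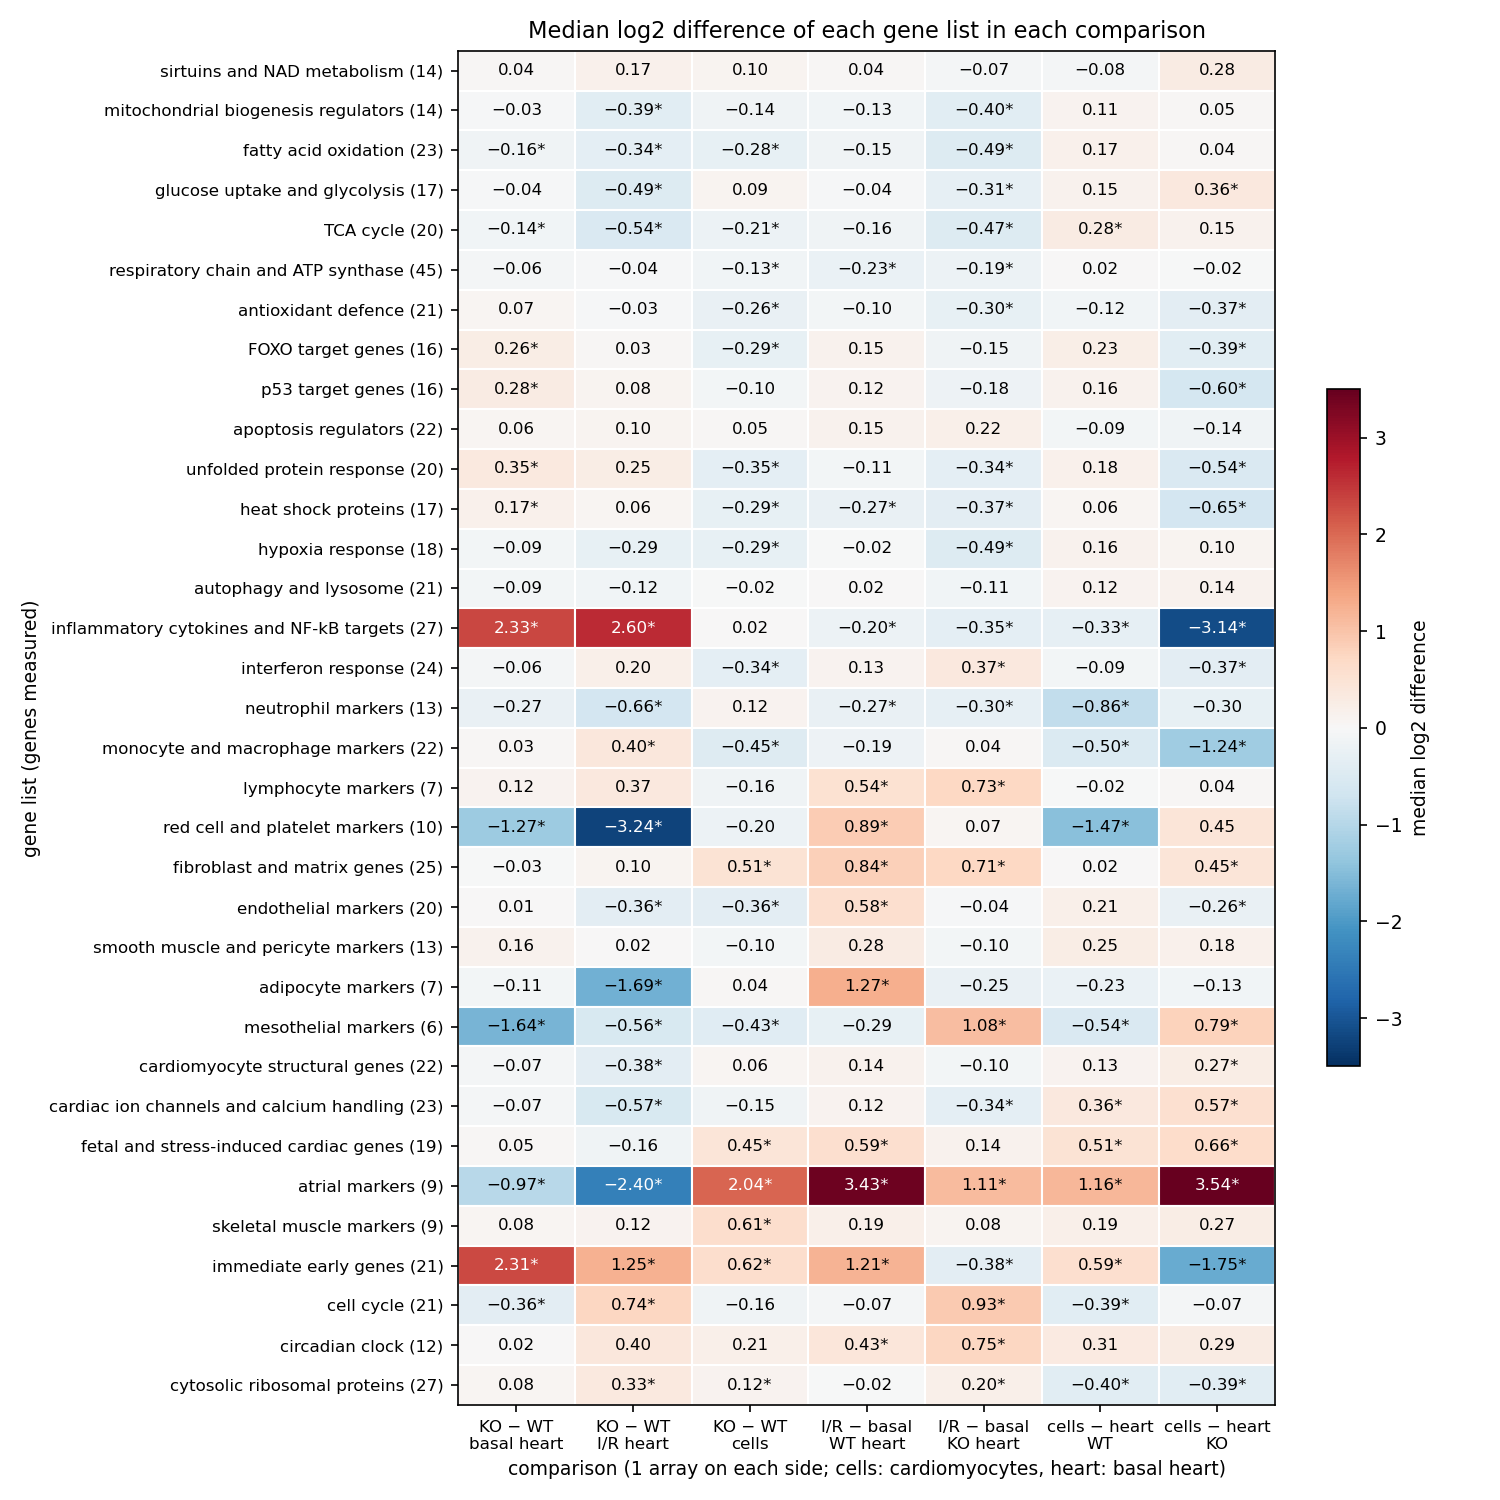
Median log2 difference of each of 34 fixed gene lists (rows) in the 7 single comparisons of arrays (columns), with colour for the value and a star where the median lay outside the central 95% of 10000 expression-matched random lists. Inflammatory genes stood at 2.33 and 2.60 for KO minus WT in basal and I/R heart and at 0.02 in cardiomyocytes, atrial markers at -0.97, -2.40 and 2.04, and the signs of the TCA cycle in basal heart (-0.14), ribosomal proteins for I/R in KO (0.20) and the respiratory chain in cardiomyocytes (-0.13) turned under median scaling (0.06, -0.11 and 0.00341).

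The comparison of basal hearts asks what the deletion changes before injury. The KO heart array held much higher levels of immediate early and inflammatory transcripts, and of a few inducible heat shock transcripts, than the WT array, and much lower levels of globins and mesothelial transcripts. Fos (Entrez Gene 14281) was 7.06 ± 0.13 higher, a 133-fold difference, and the stress-induced transcription factor Atf3 (Entrez Gene 11910) was 6.13 ± 0.12 higher. Ccl4 (Entrez Gene 20303), a chemokine that draws monocytes, was 6.73 ± 0.12 higher, and Hspa1a (Entrez Gene 193740) was 5.59 ± 0.10 higher. Hba-a1 (Entrez Gene 15122) stood at -6.30 ± 0.08 and Hbb-b1 (Entrez Gene 15129) at -5.92 ± 0.07, which are 78.6-fold and 60.7-fold lower on the KO array.

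Of 9707 genes detected on both basal arrays, 224 were at least 2-fold higher and 69 at least 2-fold lower in KO. All 21 measured immediate early genes were higher, 15 of the 17 detected ones by 2-fold or more, with a list median of 2.31. They included Egr2 (4.91 ± 0.16), Egr1 (4.83 ± 0.08) and Egr3 (4.44 ± 0.11), and Gadd45b was 4.34 ± 0.16 higher. In the inflammatory list (median 2.33) 26 of 27 genes were higher, among them Il1b (5.11 ± 0.11), the neutrophil chemoattractant Cxcl1 (4.76 ± 0.08) and the cytokine signalling inhibitor Socs3 (4.26 ± 0.09). Ccl3 and Tnf, not detected on the WT array, were at least 90.7-fold and 42.6-fold higher, and Hspa1b at least 30.0-fold higher. Heat shock proteins (median 0.17) were higher for 15 of 17 genes, 5 of the 15 detected ones by 2-fold or more, with Dnajb1 at 3.54 ± 0.07. Of the fetal and stress-induced cardiac genes, the stress cytokine Gdf15 (3.84 ± 0.16), Nmrk2 (2.42 ± 0.09), the calcineurin regulator Rcan1 (2.27 ± 0.09) and Xirp1 (1.99 ± 0.12) were higher, while the list median was 0.05. FOXO targets (0.26), p53 targets (0.28) and the unfolded protein response (0.35) also stood above their random lists, with Irs2 at 2.88 ± 0.12, Plk3 at 3.08 ± 0.17, the cell cycle inhibitor Cdkn1a at 1.59 ± 0.08 and Ddit3 at 1.68 ± 0.09. Fatty acid oxidation genes stood at -0.16, and TCA cycle genes at -0.14, a sign that turned to 0.06 under median scaling. Members of the latter list were the pyruvate dehydrogenase subunit Pdhb at -0.62 ± 0.11 and the citrate synthase Cs at -0.47 ± 0.09.

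Markers of other cell types differed beside these groups. Red cell and platelet genes had a median of -1.27, with Alas2 at least 25.9-fold lower in KO basal heart. Neutrophil markers had a median of -0.27, with S100a8 at least 31.1-fold lower, but 5 of 13 were higher, among them the receptors Clec4d (1.79 ± 0.14) and Fpr2 (1.05 ± 0.15). Mesothelial markers, which line the heart surface, had a median of -1.64, with Upk3b at -3.59 ± 0.18 and Krt8 at -1.14 ± 0.21. On both basal arrays 3 of 10 red cell and platelet, 3 of 13 neutrophil and 2 of 6 mesothelial genes were detected. Atrial markers stood at -0.97, with the natriuretic peptide Nppa at -1.21 ± 0.08, and cell cycle genes, of which 8 of 21 were detected on both arrays, at -0.36. The endothelial list had a median of 0.01 over members that went both ways, from the receptor Aplnr at -2.17 ± 0.18 to the tight junction gene Cldn5 at 2.15 ± 0.09. Macrophage markers had a median of 0.03, with Cd14 at 1.85 ± 0.11. The fibroblast list had a median of -0.03 and a mean of 0.32, with Ccn2 at 1.80 ± 0.06 and Timp1 at 1.44 ± 0.10. Other genes lower in KO were Serpina3g (-2.06 ± 0.18), Ankrd37 (-1.88 ± 0.19), Wdr92 (-1.84 ± 0.17), Gpc3 (-1.82 ± 0.14), Tmem119 (-1.67 ± 0.19) and Il16 (-1.49 ± 0.19). In all, 12 lists stood outside their random lists. Other processing settings gave 111 to 585 genes at 2-fold or more, with the lowest count from the gene-level table and the highest without the detection filter.

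**Figure D2:**
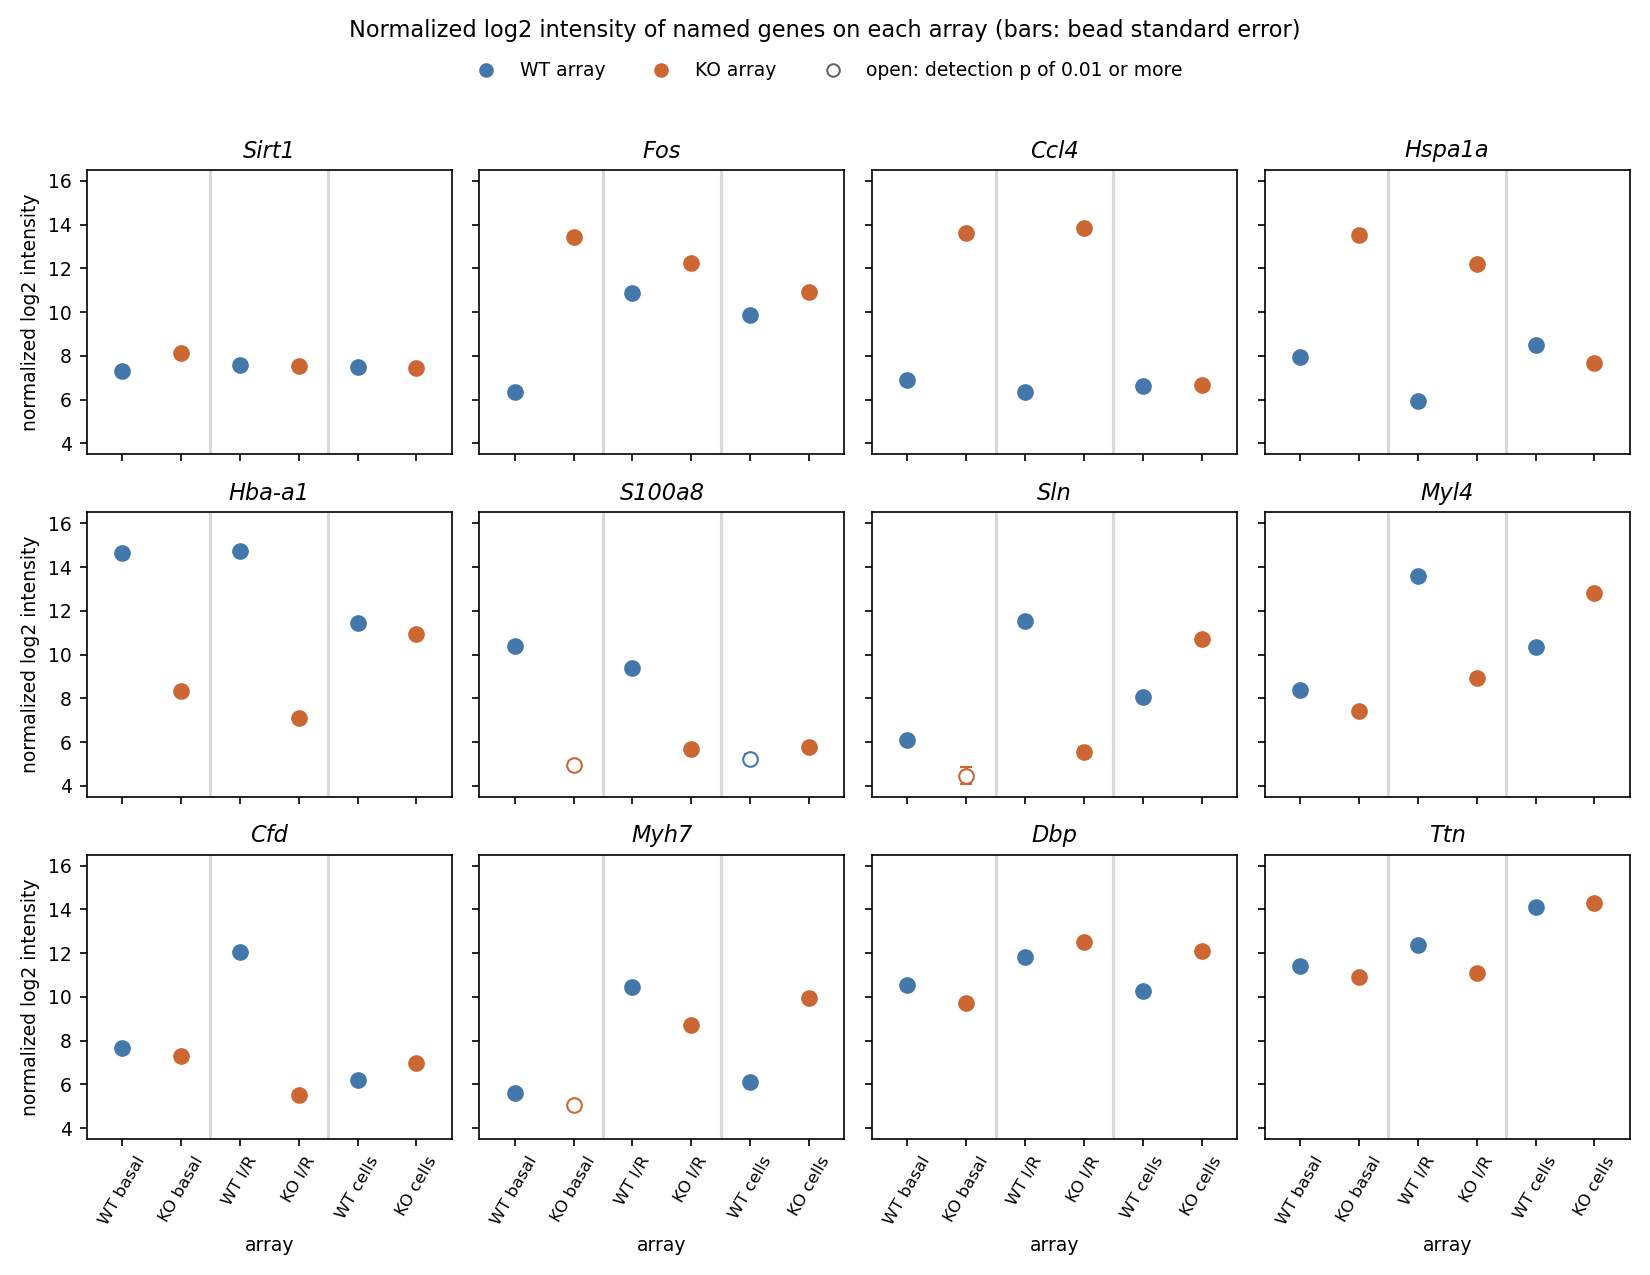
Normalized log2 intensity of 12 genes (panels) on each of the 6 arrays, with bars for the standard error from the beads and open markers where the detection p-value was 0.01 or more. Fos and Ccl4 were 7.06 and 6.73 higher on the KO than on the WT basal heart array, and Hba-a1 stood at 14.64 and 14.74 on the WT heart arrays against 8.34 and 7.09 on the KO heart arrays.

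The comparison of hearts after I/R asks whether injured hearts differ by genotype. Inflammatory genes were again far higher on the KO array, as were a few inducible heat shock genes in a list with a median of 0.06. Macrophage and cell cycle genes were higher too. Genes of the TCA cycle, glycolysis, fatty acid oxidation, ion channels, endothelium, red cells, fat and atrium were lower. The respiratory chain list stood at -0.04, with 22 genes higher and 23 lower. Ccl4 was 7.52 ± 0.12 higher (184-fold), Hspa1a 6.29 ± 0.12, Il1b 5.65 ± 0.17 and the monocyte chemokine Ccl7 4.53 ± 0.09. Hba-a1 stood at -7.65 ± 0.11, the adipocyte protease complement factor D, Cfd (Entrez Gene 11537), at -6.53 ± 0.19, and the atrial calcium pump regulator sarcolipin, Sln (Entrez Gene 66402), at -5.96 ± 0.21. Of 10074 detected genes, 458 were at least 2-fold higher and 312 at least 2-fold lower, and 17 lists stood outside their random lists.

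In the inflammatory list (median 2.60) 25 of 27 genes were higher, with Socs3 at 3.96 ± 0.08, Cxcl1 at 3.86 ± 0.08 and the I/R bounds of at least 78.4-fold for Ccl3, 54.3-fold for Cxcl2 and 37.1-fold for Tnf. Among immediate early genes (median 1.25) 17 of 21 were higher, with Atf3 at 3.67 ± 0.11 and Egr3 at 3.16 ± 0.08. Other genes higher in KO were Cd83 (3.93 ± 0.10), the apoptosis inhibitor Bcl2a1d (3.49 ± 0.12) and cholesterol 25-hydroxylase Ch25h (3.48 ± 0.11). Macrophage markers had a median of 0.40 and were higher for 18 of 22 genes, with Cd14 at 1.93 ± 0.09, Aif1 at 1.63 ± 0.12 and Cd68 at 1.31 ± 0.19. Cell cycle genes had a median of 0.74 and were higher for 20 of 21 genes, with the spindle gene Prc1 at 1.38 ± 0.13 and thymidylate synthase Tyms at 1.26 ± 0.12. Ribosomal protein genes stood at 0.33.

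TCA cycle genes had a median of -0.54 and were lower for 17 of 20 genes, with Dlst at -0.96 ± 0.06 and Ogdh at -0.90 ± 0.08. The medians were -0.49 for glycolysis, with Pkm at -1.22 ± 0.09, -0.39 for mitochondrial biogenesis regulators, with Ppargc1b at -0.96 ± 0.08, and -0.34 for fatty acid oxidation, with the acyl-CoA synthetase Acsl1 at -1.31 ± 0.09 and Decr1 the other way at 1.44 ± 0.07. Ion channel and calcium handling genes (median -0.57) were lower for 22 of 23 genes, with the potassium channel Kcnh2 at -1.41 ± 0.11, the sodium-calcium exchanger Slc8a1 at -1.27 ± 0.09 and the ryanodine receptor Ryr2 at -0.96 ± 0.11. Cardiomyocyte structural genes stood at -0.38, with titin (Ttn) at -1.27 ± 0.09, and endothelial markers at -0.36, with VE-cadherin (Cdh5) at -1.95 ± 0.10. Red cell and platelet genes stood at -3.24, neutrophil markers at -0.66 with S100a8 at -3.71 ± 0.15, adipocyte markers at -1.69 and mesothelial markers at -0.56. Of these lists, in this order, 3 of 10, 4 of 13, 2 of 7 and 3 of 6 genes were detected on both arrays. Atrial markers stood at -2.40, with the atrial light chain Myl4 at -4.68 ± 0.07 and Mybphl at -3.74 ± 0.17. Nfib (-2.44 ± 0.12), Stard10 (-2.40 ± 0.10) and Ddit4 (-2.35 ± 0.11) were also lower. The count at 2-fold or more was 770 and ran from 253 without background correction to 993 over other settings. The larger side turned with the gene-level table.

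Both heart comparisons shared many genes. Across 9070 genes, which are not independent replicates, the differences of KO and WT in basal and I/R heart correlated with a Pearson r of 0.54 and a Spearman rho of 0.47. A total of 94 genes were at least 2-fold higher in KO in both, where 8.48 were expected if independent, and 19 were lower in both, where 2.14 were expected. Between hearts and cardiomyocytes the Pearson correlations were 0.04 (basal) and 0.07 (I/R), with Spearman values of 0.05 and 0.08.

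The comparison of cardiomyocytes asks what the deletion changes in the cells in which it was made. The KO array held higher levels of slow myosin, atrial and matrix transcripts and lower levels of macrophage, endothelial and fatty acid oxidation transcripts, while the inflammatory list stood at 0.02. Myh7 (Entrez Gene 140781), the slow myosin heavy chain of fetal and stressed ventricle, was 3.87 ± 0.14 higher, a 14.6-fold difference. On this KO array 2 of 4 Xist probes were detected, against 0 on the other arrays, although the labels give male mice. They lay at log2 5.39 and 5.83, near the lowest detected level of 5.34, and the Y-linked gene Ddx3y was detected on this array too. Whether its label is right was not settled. Of 9935 detected genes, 135 were at least 2-fold higher and 95 at least 2-fold lower. Atrial markers were higher for 9 of 9 genes (median 2.04), with Mybphl at 2.82 ± 0.10, Sln at 2.62 ± 0.08, Myl4 at 2.46 ± 0.05 and Dkk3 at 2.21 ± 0.11. Fetal and stress-induced genes were higher for 15 of 19 genes (median 0.45), with Nppa at 1.51 ± 0.06 beside Myh7.

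The mitochondrial folate enzyme Mthfd2 (3.12 ± 0.09) and Asns (2.39 ± 0.12), an enzyme of amino acid synthesis, were also higher in KO cardiomyocytes, as were cartilage oligomeric matrix protein Comp (3.24 ± 0.16), the methyltransferase Inmt (2.99 ± 0.07), Angptl7 (2.84 ± 0.24) and Ecrg4 (2.58 ± 0.15). Fibroblast and matrix genes were higher for 22 of 25 genes with a median of 0.51, and 0 of them reached 2-fold, with Timp1 at 0.97 ± 0.12 and Col1a1 at 0.88 ± 0.11. Immediate early genes had a median of 0.62 and were higher for 17 of 21 genes, with Atf3 at 1.49 ± 0.11. Skeletal muscle markers stood at 0.61, with skeletal actin Acta1 at 1.09 ± 0.07. The clock output genes Dbp and Ciart were 1.85 ± 0.07 and 1.58 ± 0.18 higher, and the circadian median was 0.21. Fatty acid oxidation genes were lower for 18 of 23 genes (median -0.28), with the pyruvate dehydrogenase kinase Pdk4 at -1.78 ± 0.07 and the thiolase Acaa2 at -0.77 ± 0.06. The TCA cycle stood at -0.21, antioxidant genes at -0.26, FOXO targets at -0.29, the unfolded protein response at -0.35, heat shock proteins at -0.29, hypoxia genes at -0.29 and interferon genes at -0.34. The mean of the unfolded protein response was -0.08, with 3 detected genes at least 2-fold higher, among them Asns, and 2 at least 2-fold lower. The respiratory chain stood at -0.13 and turned to 0.00341 under median scaling, and ribosomal proteins stood at 0.12.

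Macrophage markers had a median of -0.45 in KO cardiomyocytes, with Cd163 at -1.29 ± 0.13 and Csf1r at -1.08 ± 0.13, and Fcna (-2.15 ± 0.20), Retnla (-2.34 ± 0.20) and the lymphatic and macrophage receptor Lyve1 (-1.68 ± 0.17) were lower as well. Endothelial markers stood at -0.36, with Gpihbp1 at -1.03 ± 0.09, and mesothelial markers at -0.43. The glucocorticoid-activating enzyme Hsd11b1 (-2.01 ± 0.09), the glutathione transferase Gsta1 (-1.92 ± 0.20), Sema5a (-1.85 ± 0.18), Tmc7 (-1.77 ± 0.11), Fam107a (-1.76 ± 0.21) and the protease Adamts9 (-1.67 ± 0.10) were lower. Dusp26, Chad and Il1b were at least 5.70-fold, 4.06-fold and 3.35-fold higher, and Ttc27 and Gpr137b-ps at least 7.24-fold and 3.42-fold lower. In all, 19 lists stood outside their random lists, and other settings gave 71 to 419 genes at 2-fold or more.

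The I/R effect asks how the heart differs from the basal state 24 h after reperfusion. Matrix, atrial, circadian and lymphocyte gene lists stood higher after I/R in both genotypes and cell cycle genes in KO, and lists of mitochondrial metabolism and heat shock stood lower. Interferon genes had medians of 0.13 in WT and 0.37 in KO, and only the latter stood outside its random lists. Fetal genes stood outside theirs in WT, at 0.59, and not in KO, at 0.14 with 10 genes higher and 9 lower. None of these lists was called by camera with an estimated correlation, where the smallest adjusted p = 0.646 and where 2 residual degrees of freedom hardly allow a call. Genes detected on every array with small p-values averaged over both genotypes included midkine Mdk (log2 1.82, SE 0.30), the M-band gene Myom2 (1.67, SE 0.28), the collagen Col3a1 (1.79, SE 0.31) and lipocalin Lcn2 (-1.73, SE 0.26). The limma fit called 0 genes, with 1253 at an unadjusted p-value under 0.05 (699 higher, 554 lower) and the smallest adjusted p = 0.362. With trend and robust options 11 genes were called. The same sign in both genotypes was seen for 7559 genes, of which 135 were at or beyond 2-fold in both. The fit of the 4 heart arrays, which is also the fit without either cardiomyocyte array, called 416 genes (240 higher, 176 lower). For the I/R effect averaged over 2 genotypes, 186 genes were called without WT basal heart, 38 without KO basal heart and 0 without either I/R array. In the 4 heart arrays Dkk3 rose by 3.10 (SE 0.27), Inmt by 2.46 (SE 0.27), Dbp by 2.03 (SE 0.29), Col3a1 by 1.79 (SE 0.27) and Per1 by 1.36 (SE 0.27). Ccl7 fell by 2.11 (SE 0.29), Hspa1a by 1.65 (SE 0.27) and the clock activator Arntl by 1.04 (SE 0.29). The errors and calls of this fit again rest mostly on the variance shared by all genes.

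Camera called 15 lists for the I/R effect with the preset correlation, 7 higher and 8 lower, and 0 with an estimated correlation. Fibroblast and matrix genes rose with a median of 0.78 (adjusted p = 5.62e-08, and adjusted p = 0.646 with an estimated correlation), and 11 of 25 passed when adjusted over the list alone. Atrial markers rose with a median of 2.74 (adjusted p = 0.000239, and adjusted p = 0.754 with an estimated correlation), and 2 of 9 passed when adjusted over the list alone. Circadian genes stood at 0.60 (adjusted p = 0.00152, 6 passing when adjusted over the list alone) and lymphocyte markers at 0.58 (adjusted p = 0.00692, 3 passing when adjusted over the list alone), both with adjusted p = 0.646 with an estimated correlation. Cell cycle genes stood at 0.44 (adjusted p = 0.000969, and adjusted p = 0.807 with an estimated correlation), with -0.07 in WT, where 14 of 21 genes were lower, and 0.93 in KO. Interferon genes stood at 0.23 (adjusted p = 0.0206) and fetal genes at 0.39 (adjusted p = 0.0241), both with adjusted p = 0.754 with an estimated correlation.

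The lists that fell were fatty acid oxidation (-0.32, adjusted p = 0.000159), the respiratory chain (-0.23, adjusted p = 0.000383), mitochondrial biogenesis (-0.27, adjusted p = 0.00692), hypoxia (-0.25, adjusted p = 0.0119) and neutrophil markers (-0.32, adjusted p = 0.0241), all with adjusted p = 0.646 with an estimated correlation. Heat shock proteins (-0.40, adjusted p = 0.000792), the TCA cycle (-0.28, adjusted p = 0.00557) and antioxidant genes (-0.23, adjusted p = 0.0206) had adjusted p = 0.754 with an estimated correlation. Each of these medians was under 0 in both genotypes, but that of hypoxia genes was -0.02 in WT, with 9 genes higher and 9 lower, against -0.49 in KO. When adjusted over the list alone, 1 of 13 neutrophil genes passed and 0 genes of the other lists that fell, against 2 of 19 fetal genes and 0 cell cycle and interferon genes among the lists that rose. Over all genes 0 passed in any list.

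In WT hearts the I/R array stood out by atrial, adipocyte and immediate early transcripts. Sln was 5.41 ± 0.14 higher than on the basal array (42.6-fold), Myl4 (Entrez Gene 17896) 5.20 ± 0.07, Myh7 4.88 ± 0.17, the atrial light chain Myl7 4.86 ± 0.16 and Fos 4.52 ± 0.13. Atrial markers were higher for 9 of 9 genes (median 3.43), and adipocyte markers, of which 2 of 7 were detected on both arrays, stood at 1.27 with Cfd at 4.38 ± 0.09. Immediate early genes stood at 1.21, with Egr1 at 4.14 ± 0.08. Fibroblast and matrix genes (median 0.84) were higher for 23 of 25 genes, with Col3a1 at 1.66 ± 0.18, Col1a1 at 1.49 ± 0.13 and the metalloproteinase Mmp14 at 1.45 ± 0.11. Endothelial markers were higher for 18 of 20 genes (median 0.58), with Vwf at 1.22 ± 0.06, and fetal genes stood at 0.59, circadian genes at 0.43 with Per1 at 1.38 ± 0.10, and lymphocyte markers at 0.54. Red cell and platelet genes stood at 0.89, with the platelet chemokine Ppbp at 1.67 ± 0.15 and Hba-a1 at 0.10 ± 0.06. Hbb-b2, not detected on the WT basal array, was at least 20.7-fold higher. Ccl7 (-2.82 ± 0.10), Fcna (-2.45 ± 0.14), Ccl6 (-2.27 ± 0.15), Lcn2 (-2.06 ± 0.15) and Ifi205 (-2.03 ± 0.09) were lower after I/R. Heat shock proteins stood at -0.27, the respiratory chain at -0.23, neutrophil markers at -0.27 and the inflammatory list at -0.20. Of 10122 detected genes, 207 were at least 2-fold higher and 188 at least 2-fold lower. Other settings gave 115 to 527 in all, and the larger side turned under median scaling.

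In KO hearts the I/R array was higher in matrix, cell cycle, clock and atrial genes and lower in metabolic, stress and inflammatory genes. Angptl7 was 3.24 ± 0.27 higher, Dbp (Entrez Gene 13170) 2.77 ± 0.08, Dkk3 2.76 ± 0.16, Inmt 2.64 ± 0.06, the histone gene H2ac15 2.64 ± 0.17 and Nppa 2.42 ± 0.08. Rcan1 (-2.98 ± 0.10), the activin subunit Inhba (-2.53 ± 0.25), Fcna (-2.40 ± 0.16), Ano10 (-2.28 ± 0.09) and the protease Adamts4 (-2.14 ± 0.14) were lower. Cell cycle genes were higher for 21 of 21 measured genes (median 0.93), of which 8 were detected on both arrays and 2 of those reached 2-fold, with the DNA methylation factor Uhrf1 at 1.55 ± 0.18. Fibroblast genes were higher for 20 of 25 genes (median 0.71), with Col3a1 at 1.91 ± 0.18, and atrial markers stood at 1.11. Circadian genes stood at 0.75, with Arntl at -1.76 ± 0.24, lymphocyte markers at 0.73, interferon genes at 0.37 and mesothelial markers at 1.08, of which 3 of 7 lymphocyte and 2 of 6 mesothelial genes were detected on both arrays. Fatty acid oxidation genes were lower for 20 of 23 genes (median -0.49), with Acot1 at -1.06 ± 0.08, and TCA cycle genes for 18 of 20 (median -0.47). The medians were -0.49 for hypoxia, -0.40 for mitochondrial biogenesis, with Ppargc1b at -1.23 ± 0.08, -0.37 for heat shock, with Hspa1b at -2.05 ± 0.11, -0.34 for ion channels, -0.31 for glycolysis, -0.30 for antioxidant and -0.30 for neutrophil genes. Immediate early genes stood at -0.38, with Ccn1 at -2.05 ± 0.16, and the inflammatory list at -0.35. Red cell and platelet genes had a median of 0.07 and a mean of -0.16, and ribosomal proteins stood at 0.20, which turned to -0.11 under median scaling. Of 9723 detected genes, 251 were at least 2-fold higher and 192 at least 2-fold lower. Other settings gave 132 to 736 in all, and the larger side turned under median scaling.

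The responses of both genotypes correlated across genes, which are not independent replicates, with a Pearson r of 0.38 and a Spearman rho of 0.35. They shared 51 genes at least 2-fold higher, where 4.84 were expected if independent, and 31 at least 2-fold lower, where 2.93 were expected.

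The difference of the I/R responses, KO less WT, asks whether the deletion alters the response to I/R, and rests on 1 array per group. The response was lower in KO for atrial, adipocyte, immediate early and endothelial genes and for the median of the red cell and platelet list. It was higher for cell cycle, mesothelial and circadian genes. Cfd differed by -6.16 ± 0.22, Fos by -5.68 ± 0.16, Egr1 (Entrez Gene 13653) by -4.52 ± 0.11, Ccn1 by -3.97 ± 0.26 and Myl4 by -3.71 ± 0.11. Serpina3g differed by 2.53 ± 0.28, the transcription elongation cyclin Ccnt2 by 2.11 ± 0.18, Upk3b by 2.04 ± 0.21, Cdkn3 by 1.98 ± 0.31 and the endothelial factor Sox18 by 1.95 ± 0.16. The list medians were -1.58 for immediate early, -1.44 for red cell and platelet, -1.40 for adipocyte, -1.39 for atrial and -0.62 for endothelial genes. Against these stood 1.09 for mesothelial, 1.07 for cell cycle, 0.52 for circadian and 0.39 for macrophage genes. Members of the red cell and platelet list went both ways, with Hba-a1 at -1.36 and Hbb-b1 at -0.67 but Alas2 at 0.19 and Slc4a1 at 0.17. Smooth muscle markers stood at -0.46, fetal genes at -0.43, ion channels at -0.39, hypoxia genes at -0.39, glycolysis at -0.31, the TCA cycle at -0.29 and fatty acid oxidation at -0.25. Of 9366 genes detected on the 4 heart arrays, 281 had a difference of responses of 2-fold or more upward and 252 downward. Other settings gave 150 to 1031 in all, and the larger side turned under some of them.

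Cardiomyocytes were also compared with basal heart, to describe the isolated cells against the whole tissue. Titin, ion channel and atrial genes stood higher in the cells of both genotypes, and macrophage and inflammatory genes stood lower. The list of cardiomyocyte structural genes, which holds Ttn, had an averaged median of only 0.19. Camera with the preset correlation did not call it (adjusted p = 0.0732), and 5 of 22 genes passed when adjusted over the list alone. Averaged over genotypes, the limma fit gave Ttn at 3.04 (SE 0.35) and the calcium channel subunit Cacna2d1 at 1.92 (SE 0.26), with the interferon-induced Ifi27l2a at -2.27 (SE 0.24) and the macrophage transglutaminase F13a1 at -2.19 (SE 0.25). The fit called 0 genes, with 2702 at an unadjusted p-value under 0.05 (1506 higher, 1196 lower), the smallest adjusted p = 0.0590, and 434 genes (214 higher, 220 lower) under 0.1. The same sign in both genotypes was seen for 8573 genes, of which 328 were at or beyond 2-fold in both. For cardiomyocyte minus basal heart averaged over 2 genotypes, leave-one-out gave 519 genes without WT basal heart, 96 without KO basal heart, 1685 without WT cardiomyocytes, 204 without KO cardiomyocytes and 0 without either I/R array, and moderated variances with trend and robust options gave 695.

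Camera called 8 lists for cells against heart with the preset correlation, each with adjusted p = 0.839 with an estimated correlation. Ion channel genes (median 0.46, adjusted p = 0.0171) and atrial markers (2.35, adjusted p = 0.0171) rose, with 5 of 23 and 0 of 9 genes passing when adjusted over the list alone. Inflammatory genes (-1.87, adjusted p = 7.36e-11, 11 of 27 passing when adjusted over the list alone) and macrophage markers (-0.87, adjusted p = 2.72e-06, 8 of 22 passing when adjusted over the list alone) fell. The inflammatory median was -0.33 in WT and -3.14 in KO, whose basal heart array stood high, and the macrophage median -0.50 and -1.24. Ribosomal proteins (-0.41, adjusted p = 0.000426), neutrophil markers (-0.58, adjusted p = 0.00108) and antioxidant genes (-0.17, adjusted p = 0.0234) fell too. When adjusted over the list alone, 3 of 13 neutrophil, 1 of 21 antioxidant and 0 of 27 ribosomal genes passed. Immediate early genes stood at -0.45 (adjusted p = 0.0171), with 0.59 in WT and -1.75 in KO, and 0 of 21 passed when adjusted over the list alone.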

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

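All tests in this part except those on further adipocyte and further atrial genes were chosen after the result was seen, and intervals are 95% intervals from 2000 resamples of genes, which do not cover differences between animals.

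Inflammatory and immediate early genes were higher on both KO heart arrays, with list medians of 2.33 and 2.31 in basal and 2.60 and 1.25 in I/R heart. Blood leukocytes left in the KO hearts were argued against by 8 abundant blood transcripts, 7 of them also in the neutrophil or red cell lists, whose median for KO minus WT was -4.86 (-5.92 to -2.94) in basal and -3.84 (-6.59 to -2.31) in I/R heart, with S100a8 at log2 10.38 in WT and 4.97 in KO basal heart. A deletion effect within cardiomyocytes that is kept in isolated cells was examined over 12 inflammatory genes. These were at or beyond 2-fold on both KO heart arrays and detected on at least 1 cardiomyocyte array. Their median was -0.40 (-0.83 to 0.15) in cells and 3.96 (2.62 to 5.88) in hearts, the latter raised by this choice. If the label of the KO cardiomyocyte array, left open below, is right, this argues against such an effect for these genes at the median, although Il1b was higher in the KO cells. The 9 immediate early genes chosen in the same way had medians of 1.00 (0.62 to 1.22) in cells and 3.49 (1.91 to 4.39) in hearts. These medians cannot decide on such an effect, as a part or the whole of the difference, because the WT cells were themselves raised. WT cardiomyocytes minus WT basal heart was 0.59 at the median of the immediate early list, with 14 genes higher and 7 lower. It was 2.93 for Egr1 and 1.81 for Atf3. A raised WT level can shrink KO minus WT in cells, and the choice of genes raised the value in hearts. Such an effect therefore stays open for the immediate early genes. Handling or perfusion of the KO hearts before RNA extraction could raise these genes and, with 1 array per group, cannot be told apart from a deletion effect that needs the intact heart or from effects of tamoxifen or Cre, since the ratio of the inflammatory medians in basal over I/R heart, 0.893 (0.798 to 2.49, 27 genes), only restates that both hearts share the pattern.

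KO minus WT in cardiomyocytes resembled the I/R response across 9070 genes, with a Pearson r of 0.30 with the response in WT and 0.33 with that in KO. The 187 genes at or beyond 2-fold in cardiomyocytes differed by -0.0375 (-0.16 to 0.07) between the basal hearts in the direction of the cells. In the cells they differed by 1.21, a value raised by this choice of genes. If the label of the KO cardiomyocyte array is right, this argues, for these genes on these arrays, against a deletion effect that is the same in the unoperated heart. Cardiomyocyte RNA taken from an operated or otherwise stressed KO heart may give this pattern, but the median of 0.86 (0.70 to 1.00) in that direction over the 82 genes at or beyond 2-fold in both I/R responses only restates the correlations. Atrial tissue in both the KO cardiomyocyte and the WT I/R samples may add to it, as the atrial list (9 genes, of which Nppa, Myl4 and Mybphl are also in the fetal list) was high in KO cardiomyocytes, with Nppa at log2 14.81 and Myl4 at 12.82, and the r with the KO response over that with the WT response, 1.12 (1.03 to 1.22), decides nothing because the atrial list was also higher in the KO response at 1.11 (0.35 to 2.42). Both cannot be told apart from a deletion effect that appears in isolated cells, because the labels give 1 KO cardiomyocyte sample and no surgery for it, and whether its label is right stays open.

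Adipocyte and atrial genes were higher on the WT I/R than on the WT basal array, with Cfd at log2 12.05 against 7.67, Adipoq at 7.40 against 4.78, where it was not detected, and Myl4 at 13.60 against 8.40. I/R raising adipocyte genes in the heart stays open, because the adipocyte list, at -0.25 (-0.67 to -0.08) in KO and 1.27 in WT, had 2 of 7 genes detected on both KO heart arrays and a rise in WT alone was not tested. For fat tissue in the sample, further adipocyte genes had a median of 0.0117 (-0.55 to 2.27) over 4 of 10 measured genes, all of them also read on the KO heart arrays, with Plin4 at 10.38 against 10.70 and Scd1 at 10.16 against 7.89, and for atrial tissue, further atrial genes had a median of 0.32 (-0.02 to 0.43) over 6 of 9, of which Kcnj3 and Gja5 are also in the ion channel list. Both medians met the bound written in advance against these sources (0.5 or lower, or an interval that holds 0). They are still taken as open, because fewer than 80% of either list were measured, an interval that holds 0 over so few genes excludes little, and Kcnj3, Kcnj5 and Tbx5 lay at 5.37, 5.34 and 5.24, near the lowest detected level of 5.19, but this condition was set after the values were seen.

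The following list medians had opposite signs in the contrasts compared and stood outside their random lists in both, and none of these differences was tested. Cell cycle genes went from -0.36 in basal to 0.74 in I/R heart for KO minus WT, a difference of 1.11, but only 8 of 21 were detected on both basal arrays and 0 of these reached 2-fold there. From basal heart to cardiomyocytes, KO minus WT went from 0.26 to -0.29 for FOXO targets (difference -0.54), from 0.35 to -0.35 for the unfolded protein response (-0.70), from 0.17 to -0.29 for heat shock proteins (-0.46) and from -0.97 to 2.04 for atrial markers (3.01). In cardiomyocytes the unfolded protein response had a mean of -0.08, with 3 detected genes at least 2-fold higher and 2 at least 2-fold lower. From I/R heart to cardiomyocytes KO minus WT went from 0.40 to -0.45 for macrophage markers (-0.85) and from -2.40 to 2.04 for atrial markers (4.44). The I/R response of immediate early genes was 1.21 in WT and -0.38 in KO (-1.58). Cardiomyocytes minus basal heart was -0.54 in WT and 0.79 in KO for mesothelial markers (1.34), of which 2 of 6 were detected on both KO arrays, and 0.59 and -1.75 for immediate early genes (-2.34).

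Single genes with opposite signs beyond 2-fold were also not tested. From I/R heart to cardiomyocytes, KO minus WT went from 4.53 to -1.61 for Ccl7 (-6.14) and from -4.68 to 2.46 for Myl4 (7.13). The I/R response of Fos was 4.52 in WT and -1.16 in KO (-5.68). Cardiomyocytes minus basal heart, WT then KO, was 1.81 and -2.82 for Atf3 (-4.63), and 2.93 and -1.39 for Egr1 (-4.32). For Fos it was -2.51 in KO and above 0 in WT (-6.01). The pairs were -3.20 and 2.60 for Hba-a1 (5.80), -2.65 and 2.78 for Hbb-b1 (5.44), and -1.01 and 2.59 for Upk3b (3.59).

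The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. By genotype the limma fit called 0 genes, a count that all 10 splits reach whatever the data, and the highest other split called 3. At an unadjusted p-value under 0.05 the genotype split gave 1249 genes and 3 of 10 splits gave as many. The highest other count, 1421, came from the other two of these, which with condition in the fit part only the WT from the KO I/R heart array and so hold the same genotype difference.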

How the results depend on the processing

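No test in this part was chosen after the result was seen except camera after median scaling, camera on the 4 heart arrays and counts without marker lists. Counts of genes at 2-fold or more, in the order KO minus WT in basal heart, KO minus WT in I/R heart, KO minus WT in cardiomyocytes, I/R minus basal in WT heart, I/R minus basal in KO heart and KO I/R response minus WT I/R response, were 293, 770, 230, 395, 443 and 533. They were 138, 253, 77, 115, 132 and 150 without background correction, 189, 483, 127, 200, 245 and 280 with an offset of 50, and 111, 320, 71, 134, 162 and 186 from the gene-level table, for which the cause was not tested. A larger offset or a background left in draws differences of dim genes toward 0. Without the detection filter, which adds dim genes, the counts were 585, 419, 736 and 1031 for KO minus WT in basal heart and in cardiomyocytes, the I/R effect in KO and the difference of responses. The counts kept within 1.5 times under the authors' quantile values, the series values, median scaling, the mean of detected probes, a difference beyond 3 bead standard errors and a detection p-value under 0.05. Without the marker lists that stood apart, the first 4 counts were 262, 742, 224 and 389. Of the genes at 2-fold or more, 59.5% were higher in KO I/R heart and 47.8% with the gene-level table, and after I/R 56.7% were higher in KO (46.2% under median scaling) and 52.4% in WT (46.3%). For KO I/R response minus WT I/R response the share was 52.7%, and 45.3% without background correction, 48.6% under median scaling and 44.6% with the gene-level table. Median scaling moved the median of all genes from 0.04 to -0.10 for I/R in KO and from -0.03 to 0.07 for KO minus WT in basal heart. Of 840 list medians under other settings, 573 stayed within 0.1, 264 moved by more and 3 reversed, all under median scaling, and the cause was not tested. These were TCA cycle: KO minus WT in basal heart (0.0593), respiratory chain and ATP synthase: KO minus WT in cardiomyocytes (0.00341) and cytosolic ribosomal proteins: I/R minus basal in KO heart (-0.11). Of 6445 named gene values 5282 stayed within their 95% bead error, 1162 moved by more and 1 reversed, Ccl7: KO I/R response minus WT I/R response, at -0.18 in the gene-level table, and the cause was not tested. Reversals were counted only for lists that stood outside their random lists and for named genes at 2-fold or more. Other changes of sign are among the values that stayed or moved. With trend and robust options 8 genes were called for the genotype effect averaged over 3 conditions, 11 for the I/R effect averaged over 2 genotypes and 695 for cardiomyocyte minus basal heart averaged over 2 genotypes, and the cause was not tested. The last also gave 1 without background correction, 230 with an offset of 50 and 223 at a detection p-value under 0.05. The 4 heart arrays alone gave 617 and 416 for the first 2. That fit had 34.5 prior degrees of freedom, and the leave-one-out fits had 3.24 to 379. Counts from these fits rest mostly on the variance shared by all genes. Leave-one-out fits, with 1 residual degree of freedom and the lone sample of a group assumed to vary like the others, gave 0 to 617 for the genotype effect (102 without either basal heart, 0 without either I/R heart, 617 without either cardiomyocyte array), 0 to 416 for the I/R effect (186 without WT basal heart, 38 without KO basal heart, 0 without either I/R heart, 416 without either cardiomyocyte array) and 0 to 1685 for cardiomyocytes (519 without WT basal heart, 96 without KO basal heart, 0 without either I/R heart, 1685 without WT and 204 without KO cardiomyocytes). For gene lists in averaged effects, camera called 32 of 105, 0 with an estimated correlation and 36 after median scaling, 31 of them shared. Over the 4 heart arrays it called 36 of 70, 21 shared, and fatty acid oxidation, fibroblast and ribosomal lists no longer passed for genotype. No paired analysis was possible because the arrays share only replicate number 3, which does not link animals. Signal over background limits dim genes, for which bounds are given.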

Other observations

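No test is reported in this part.

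Isolated cardiomyocytes kept the transcripts of several other cell types. Beside Ttn (2.71 ± 0.07 in WT and 3.37 ± 0.07 in KO, cells minus basal heart), endothelial markers had medians of 0.21 in WT and -0.26 in KO, smooth muscle markers of 0.25 and 0.18, and fibroblast genes of 0.02 and 0.45. The epicardial and fibroblast transcription factor Tcf21 was lower at -2.23 in WT and -1.54 in KO, while the fibroblast receptor Pdgfra stood at 0.82 and 0.92. Macrophage markers had medians of -0.50 and -1.24, and 7 of 21 and 13 of 20 detected members were at least 2-fold lower. Hba-a1 was 14.64 in WT basal heart, 11.44 in WT and 10.95 in KO cardiomyocytes and 8.34 in KO basal heart. Of 9875 genes detected in WT, 268 were at least 2-fold higher and 304 lower in the cells, and of 9539 in KO, 554 were higher and 561 lower.

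The clock output gene Dbp was 1.85 ± 0.07 higher in KO than in WT cardiomyocytes, 1.28 ± 0.09 higher after I/R in WT hearts and 2.77 ± 0.08 higher in KO hearts. The time of day at which tissue was taken is not given in the sources used here.

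The labels give male mice throughout, and the values that follow leave it open whether the KO cardiomyocyte label is right. The Y-linked gene Ddx3y was detected on every array, with log2 levels from 9.85 in WT basal heart to 11.05 in KO cardiomyocytes. Xist, which is expressed from the inactive X chromosome, was read by 4 probes, of which 2 were detected on the KO cardiomyocyte array, at log2 5.39 and 5.83, and 0 on the other 5 arrays. The list of sex-linked genes had medians of 0.11, -0.07 and -0.56 for KO minus WT in basal heart, I/R heart and cardiomyocytes, and the last stood outside its random lists while its mean was -0.05.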
